A study of Mus musculus with 7 samples.

How the data were processed

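Polyadenylated RNA of LLC1, a mouse Lewis lung carcinoma line grown in culture, was sequenced in 7 libraries. The labels put 4 libraries in a wild-type group and 3 in a group in which Ddx54 was knocked down with an shRNA. The labels name no control construct for the wild-type cells and no shRNA sequence. Nothing in the labels says whether the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. A single-cell part of the same series, on immune cells sorted from tumours, was not analysed here.

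The values are raw read counts per gene symbol, as the authors deposited them in one table of 24419 genes. Trimmomatic, STAR and HTSeq and the mouse build mm10 are listed by the submitters' processing notes, without roles or versions. The gene annotation, the strand setting of the counting and the treatment of reads that match several genes are not given in the sources used here. Without a stated strand setting, reads of a gene and of an antisense gene over it cannot be told apart, and genes with near-identical copies are uncertain. The table has 0 further sample columns. Total counts ranged from 14987324 to 18673395 per library, and 9012 genes had no count in any library. Expression is given as CPM, the usual count scaled to library size, and genes at a few CPM rest on few reads and carry a wide counting error.

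Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the group, which left 11594, and libraries were scaled by TMM factors. The robust quasi-likelihood test compared the 3 knockdown libraries with the 4 wild-type libraries with no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A positive log2 fold change means higher in knockdown. The standard error (SE) is the absolute log2 fold change divided by the square root of the F statistic, which is approximate. CPM values are scaled by the TMM factors and given as mean ± SD, with n = 4 wild-type and n = 3 knockdown libraries throughout. Positions come from the GENCODE annotation of GRCm38, the assembly also called mm10, matched by symbol for 96.2% of tested genes.

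Before the data were examined, 27 gene lists were fixed from textbook knowledge of Ddx54, tumour immunity, cell state, library quality and other cell types. The 24 lists with at least 5 tested members were tested with camera, two-sided, with a preset inter-gene correlation of 0.01 and adjustment over the lists. Camera with an estimated correlation and the directional fry test were alternatives. Camera asks whether a list moves more than the other genes, while fry asks only whether its members move. Fry passed 21 of the 24 lists. The genes to be named were also fixed by rule. They include, whatever their values, Ddx54, Myc, Stat3, Rela, Nfkb1, Cd47, Cd38, Cd274, B2m and H2-K1. Next come the 10 largest rises and the 10 largest falls with adjusted p under 0.05, a mean of at least 10 CPM and no overlap between the groups' ranges, leaving out predicted and accession-like gene models, of which there was 1 among the first-ranked rises and 0 among the falls. In each list, up to 4 members past the threshold with the largest change were eligible, or the 2 with the smallest p where fewer than 2 passed. Rn45s, Trim12c, Gfra3 and Nhlh2 were added after their values were seen. Some genes that the rule takes are not reported here.

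The alternatives set beforehand were RLE and upper-quartile factors, no low-count filter, a filter of at least 50 counts in at least 3 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), the replicate number as a block, thinning to the shallowest library, and leaving out each library in turn. A correction for GC content and transcript length (loess span 0.5), removal of Rn45s, and the Myc list without members of the cell cycle lists were added after seeing the data. The test was run on simulated counts for this comparison over 11413 genes, with 200 genes changed and a further list of 30 raised by 0.4 log2 units. The test recovered 44.8% of changes of 0.5 log2 units, 82.1% of changes of 1 and 93.9% of changes of 2. There were 12 false calls among 11183 unchanged genes, which was 7.1% of all calls. Far fewer genes were changed than the 29.4% of tested genes that passed in the real comparison, so the recovery need not hold there. Camera called 0 of 26 simulated null lists drawn without correlation between genes, as did fry. No pair of libraries in a group differed by as little as sampling noise, with chi-square per degree of freedom from 8.31 to 16.3.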

Results

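Gene expression was measured in 7 libraries of cultured LLC1 cells, 4 wild-type and 3 with an shRNA against Ddx54, a nucleolar DEAD-box RNA helicase. The series title concerns lowered DDX54 in lung tumours and PD-1 blockade, and the comparison here asks how the tumour cells' own transcripts differ when Ddx54 is knocked down. The wild-type libraries held 18673395, 15293346, 15706013 and 17086680 counts, and the knockdown libraries held 16357913, 17702932 and 14987324. Rn45s, the 45S pre-ribosomal RNA, took 11.6 ± 0.83% of counts in wild-type (SD, n = 4) and 8.53 ± 0.55% in knockdown (SD, n = 3). The libraries were of polyadenylated RNA, so this share is not a measure of the ribosomal RNA in the cells.

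Ddx54 lies on chromosome 5 at 120612739 to 120628592 on the plus strand (GRCm38/mm10, protein-coding gene ENSMUSG00000029599.13). It was at 80.4, 82.5, 78.6 and 83.2 CPM in the wild-type libraries and at 45.9, 39.2 and 45.8 CPM in the knockdown libraries. The knockdown level was 53.8% of wild-type, a log2 fold change of -0.90 (SE 0.096, adjusted p = 6.55e-09, edgeR quasi-likelihood). An exact two-sided permutation test over the 35 splits gave p = 0.0286, the smallest it can give. None of the 7 libraries had a Ddx54 level that went against its label.

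Of 11594 tested genes, 1635 were higher and 1770 were lower in knockdown, and 8189 did not pass the threshold. Changes of at least 1 log2 unit were fewer, with 122 genes higher and 242 lower. The ranges of both groups did not overlap for 35.1% of tested genes, against 5.71% by chance. The median log2 fold change of all tested genes was 0.001.

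**Figure D1:**
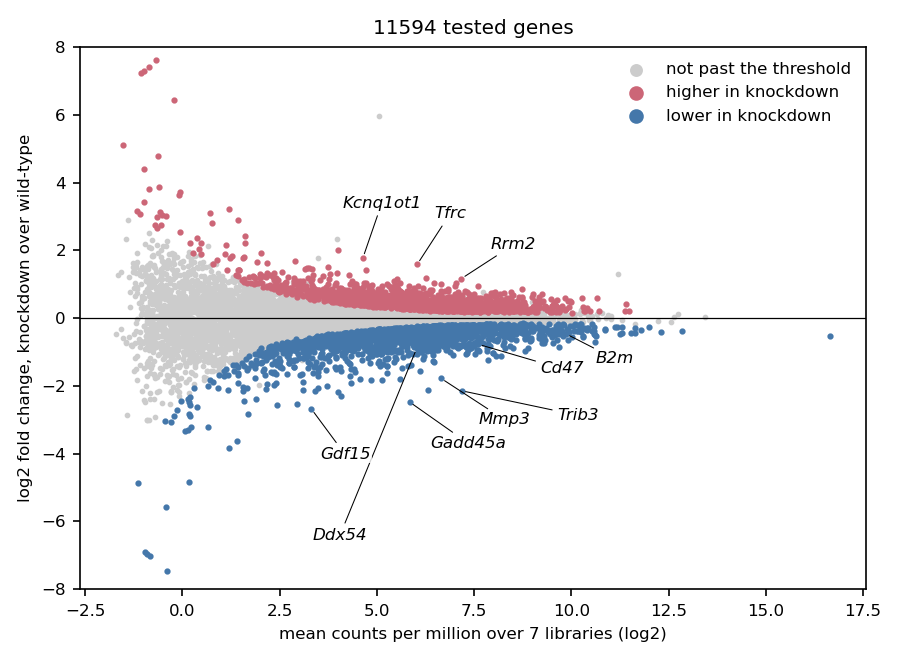
Log2 fold change (knockdown over wild-type) of each of the 11594 tested genes against its mean CPM over 7 libraries (log2 axis). Red points are the 1635 genes higher in knockdown, blue points the 1770 genes lower, and grey points did not pass an adjusted p of 0.05.

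Among the genes fixed for their part in tumour signalling and immunity, 7 fell, Ddx54 included. Myc, a growth-promoting transcription factor, fell from 151.4 ± 22.02 to 74.96 ± 5.56 CPM (log2 fold change -1.01, SE 0.093, adjusted p = 3.31e-10). Cd47, the ligand that restrains phagocytosis, fell from 236.8 ± 11.4 to 138.5 ± 11.4 CPM (-0.77, SE 0.072, adjusted p = 3.34e-10). Cd38, an ectoenzyme that consumes NAD, fell from 15.5 ± 2.67 to 7.63 ± 1.59 CPM (-1.02, SE 0.21, adjusted p = 0.000296). Stat3, a transcription factor downstream of cytokine receptors, fell by a smaller amount (-0.44, SE 0.092, adjusted p = 0.000345). B2m, the light chain of MHC class I, went from 1057 ± 80.5 to 764.5 ± 48.0 CPM (-0.47, SE 0.064, adjusted p = 6.55e-07), and the heavy chain H2-K1 from 25.2 ± 5.44 to 15.7 ± 2.16 CPM (-0.68, SE 0.17, adjusted p = 0.00232). H2-K1 has close paralogs, so its counts are uncertain. Rela (-0.11, adjusted p = 0.353) and Nfkb1 (-0.22, adjusted p = 0.248) did not pass. Cd274, which encodes PD-L1, was at 1.27 ± 0.59 CPM in wild-type and 2.34 ± 0.99 CPM in knockdown and did not pass (adjusted p = 0.294).

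**Figure D2:**
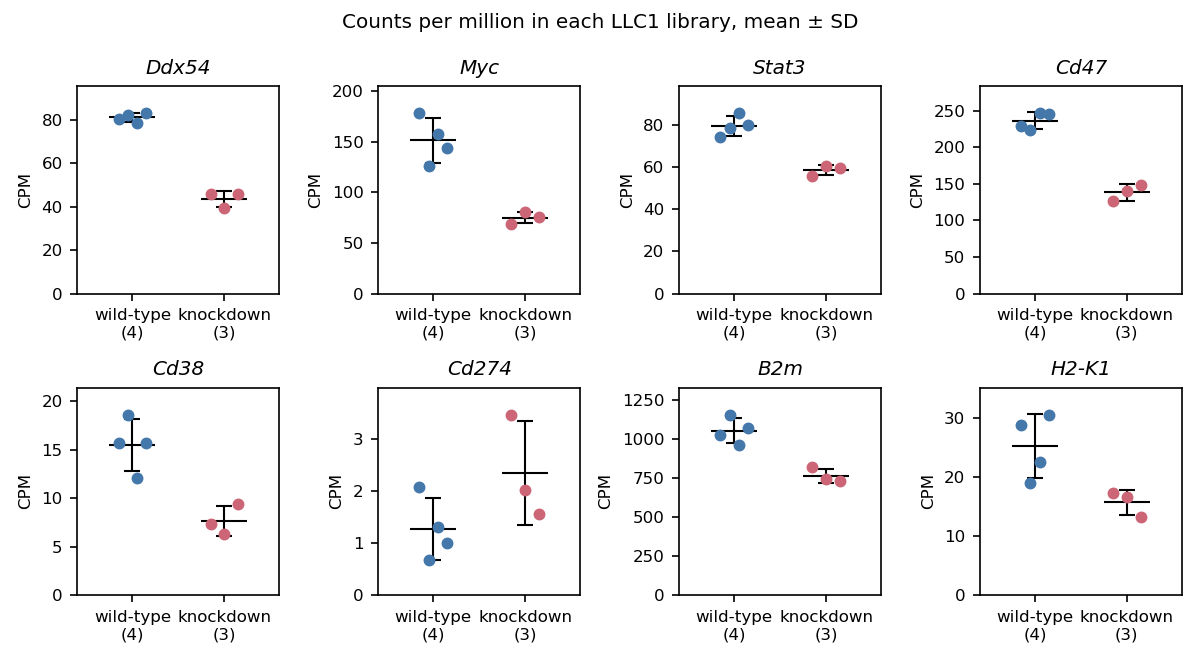
CPM (linear axes from 0) of 8 genes in each library, with 4 wild-type libraries in blue and 3 knockdown libraries in red; the horizontal mark is the mean and the bars are 1 SD. Ddx54 lies between 78.6 and 83.2 CPM in wild-type and between 39.2 and 45.9 CPM in knockdown, while the ranges of Cd274 overlap.

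The largest falls among well-expressed genes included stress-response genes. Gadd45a, a growth-arrest gene, fell from 88.4 ± 3.46 to 15.9 ± 2.002 CPM (log2 fold change -2.48, SE 0.11). Trib3, a pseudokinase induced by ATF4, fell from 216.6 ± 18.3 to 48.9 ± 7.64 CPM (-2.15, SE 0.093), and Ddit3, which encodes the stress factor CHOP, fell from 118.5 ± 23.2 to 27.4 ± 1.33 CPM (-2.11, SE 0.12). The other falls were Macrod1 (-2.29), Enox1 (-2.17), Ap3b2 (-2.15), the kinase Prkcb (-2.07), Atf3 (-2.01), Glrp1 (-1.93) and Crabp1 (-1.83), a retinoic acid-binding protein. Among the genes ranked by the naming rule, the largest rise with a stable call was Kcnq1ot1, a long noncoding RNA, from 12.2 ± 3.65 to 42.0 ± 4.19 CPM (1.78, SE 0.17). Tfrc, the transferrin receptor, rose from 35.4 ± 6.999 to 106.4 ± 0.92 CPM (1.59, SE 0.11), and the cell-cycle repressor E2f7 from 15.5 ± 1.76 to 41.2 ± 5.07 CPM (1.41, SE 0.14). Mir17hg (1.51), host of a microRNA cluster, Rbmx (1.32), Fat1 (1.31), Neurl1b (1.28), Ttll4 (1.28) and Uchl1 (1.24) also rose. Dnm3os had the largest rise of the ranked genes, 2.01 (adjusted p = 0.0303, edgeR). It lost its call without wild-type replicate 4 or without any single knockdown library (adjusted p from 0.0675 to 0.0771). Dnm3os and Kcnq1ot1 are annotated as antisense transcripts, so reads of their partners may be counted with them, and Rbmx has near-identical copies.

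Genes of DNA replication and mitosis rose together. In the S phase list 31 of 42 tested members rose (32 adjusted over the list alone), with a median log2 fold change of 0.43 and a camera adjusted p of 5.48e-19. Rrm2, a subunit of ribonucleotide reductase, rose from 94.2 ± 10.8 to 211.5 ± 5.34 CPM (1.16), and Ccne2 (1.10), Clspn (1.04) and Cdc6 (0.998) also rose. In the G2 and M phase list 32 of 42 rose (36 adjusted over the list alone; median 0.34, camera adjusted p = 4.11e-15), with Kif20b (0.77), Gtse1 (0.71), Ttk (0.65) and Dlgap5 (0.64). In the DNA repair list 16 of 45 rose and 3 fell (17 and 4 adjusted over the list alone; camera adjusted p = 0.000865), with Rad54l (0.85) and Atm (0.73). In cholesterol synthesis 9 of 24 rose and 15 did not pass (9 adjusted over the list alone; camera adjusted p = 0.00162), with Hsd17b7 (0.82), Ebp (0.73) and Acat2 (0.66). These 4 lists kept the call with an estimated correlation (adjusted p from 0.0026 to 0.0442).

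The list of the unfolded protein and integrated stress response moved in both directions, with 22 of 38 members lower and 7 higher (22 and 8 adjusted over the list alone; median -0.53, camera adjusted p = 5.82e-15). Trib3, Ddit3, Atf3 and Nupr1 fell most, Nupr1 from 50.9 ± 4.39 to 14.4 ± 1.30 CPM (-1.82). The 7 members that rose did so by 0.20 to 0.53 log2 units. All 7 encode chaperones or folding factors of the endoplasmic reticulum, so the fall of the list does not extend to them. In the glycolysis and hypoxia list 22 of 36 fell and 1 rose (24 and 1 adjusted over the list alone; median -0.41, camera adjusted p = 3.96e-11). Ddit4, a hypoxia-induced inhibitor of mTORC1, fell from 239.4 ± 6.88 to 113.6 ± 7.58 CPM (-1.08), and Ndrg1 (-0.86), the glycolytic enzyme Gpi1 (-0.80) and Pdk1 (-0.76) also fell. Immediate early genes, which respond to handling or serum, fell in 11 of 22 cases (11 adjusted over the list alone; median -0.37, camera adjusted p = 1.03e-05), with Atf3, Egr1 (-1.06), Klf4 (-0.95) and Junb (-0.75). These 3 lists kept the call with an estimated correlation (adjusted p = 0.0442 for each). Within the last list, Egr1 lost its call with the replicate number as a block (-1.04, adjusted p = 0.0717, edgeR).

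In the list of mesenchymal and extracellular matrix genes 18 of 43 fell and 1 rose (20 and 1 adjusted over the list alone; median -0.37, camera adjusted p = 1.5e-08; adjusted p = 0.0266 with an estimated correlation). The matrix metalloproteinases Mmp3 and Mmp13 fell, Mmp3 from 144.4 ± 3.06 to 42.0 ± 3.88 CPM (-1.78) and Mmp13 by -1.61, as did the collagen Col6a3 (-1.89). In the JAK-STAT list 11 of 33 fell and 22 did not pass (11 adjusted over the list alone; camera adjusted p = 0.00413; adjusted p = 0.0442 with an estimated correlation), with Socs2 (-1.43), Bcl3 (-1.35), Pim1 (-0.86) and Bcl2l1 (-0.82). The median of the JAK-STAT list was only -0.11. It was -0.031 with no low-count filter, -0.054 with the correction for GC content and length, and -0.18 without wild-type replicate 1. The next 4 calls were lost with an estimated correlation, and the last of them, immune evasion ligands, had a median of only -0.11. NF-kB targets had 11 of 28 lower (11 adjusted over the list alone; camera adjusted p = 0.000325; adjusted p = 0.0814 with an estimated correlation), with Ptgs2 (-1.34), Relb (-1.19) and Csf1 (-0.88). The TGF-beta list had 8 of 24 lower and 1 higher (8 and 1 adjusted over the list alone; camera adjusted p = 0.0167; adjusted p = 0.0814 with an estimated correlation), with Junb and Tgif1 (-0.69). Chemokines and cytokines had 7 of 16 lower (7 adjusted over the list alone; camera adjusted p = 0.00927; adjusted p = 0.152 with an estimated correlation), with Il33 (-2.83) and Il11 (-0.95). Immune evasion ligands had 6 of 16 lower (6 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00814; adjusted p = 0.0992 with an estimated correlation), among them Cd47, Cd38, Ptgs2 and Pvrl2 (-1.16), and the groups' ranges of the list mean overlapped.

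Lists of innate and adaptive immune recognition did not pass with camera. In MHC class I presentation 5 of 19 rose and 4 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.548), with Erap1 (0.84) and Psmb10 (0.79) higher and H2-K1 lower. Interferon-stimulated genes had 2 of 27 higher and 3 lower (2 and 3 adjusted over the list alone; camera adjusted p = 0.656), with Irf9 higher (0.94; adjusted p = 0.0822 without Ddx54 knockdown replicate 1) and Isg20 (-0.97) and Ifitm3 (-0.75) lower, the last from 763.3 ± 48.4 to 454.8 ± 21.7 CPM. This list had a median of 0.03, a mean of -0.04 and a test direction of lower, and it passed as lower with fry (adjusted p = 0.0112). Nucleic acid sensors had 4 of 22 higher and 2 lower (4 and 3 adjusted over the list alone; camera adjusted p = 0.774), with Tbk1 (0.58) and Eif2ak2 (0.53) higher and Irf3 (-0.48) lower. Irf3 lost its call without wild-type replicate 2 or 4 and without Ddx54 knockdown replicate 1 or 3. The call was also lost with the replicate number as a block and with the correction for GC content and length. Over these settings its adjusted p was 0.0535 to 0.11 (edgeR).

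Genes of the cytosolic ribosomal protein list were lower in knockdown. In this list 45 of 54 fell (47 adjusted over the list alone; median -0.32, camera adjusted p = 2.37e-14), including Rpl28 (-0.62), Rpl10a (-0.55) and Rpl3, from 1010 ± 54.2 to 701.6 ± 10.5 CPM (-0.53). The call was lost with an estimated correlation (adjusted p = 0.162), and ribosomal protein genes have many near-identical pseudogenes. Ribosome biogenesis factors had 10 of 52 higher and 3 lower (10 and 3 adjusted over the list alone; camera adjusted p = 0.074), with Utp20 (0.80) and Rrp12 (0.46). That list passed as higher without wild-type replicate 1 (adjusted p = 0.0465) and with fry (adjusted p = 0.0247). Other DEAD-box helicases had 10 of 29 higher and 1 lower (11 and 1 adjusted over the list alone; camera adjusted p = 0.00927; adjusted p = 0.165 with an estimated correlation), with Ddx39 (0.68) and Ddx19b (0.48) higher and Ddx50 (-0.53) lower. The Myc list rose in 13 of 33 cases and fell in 3, Myc itself and Sord (-0.65) among the latter (14 and 3 adjusted over the list alone; camera adjusted p = 0.000475; adjusted p = 0.0916 with an estimated correlation). Tfrc and Mcm5 (0.63) led its rises. The median of the Myc list was 0.16, and that of the DEAD-box list was 0.13.

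The p53 list had 9 of 30 lower and 2 higher (9 and 2 adjusted over the list alone; camera adjusted p = 0.0389), with Gdf15 (-2.69), Bbc3 (-1.26), Sesn2 (-1.17) and Ephx1 (-1.08). The median of the p53 list was only -0.12. Its camera call was lost with an estimated correlation (adjusted p = 0.0992) and without wild-type replicate 2 (adjusted p = 0.057). The call was also lost without Ddx54 knockdown replicate 3 (adjusted p = 0.0572) and with the correction for GC content and length (adjusted p = 0.0688). Oxidative phosphorylation had 7 of 42 higher and 5 lower (7 and 5 adjusted over the list alone; camera adjusted p = 0.761), with Cycs (0.49) and Cox7b (0.47) higher and Atp5d (-0.40) and Cox4i1 (-0.34) lower; its median was -0.02, its mean 0.02 and its test direction higher. Of the cell-type marker lists, the epithelial list may mark LLC1 itself, since LLC1 is a carcinoma line. In that list 6 of 28 genes could be tested and 2 fell (2 adjusted over the list alone, camera adjusted p = 0.0562). Krt18 fell from 217.5 ± 4.77 to 131.7 ± 4.02 CPM, and Krt19 also fell (-2.03). The epithelial list passed as lower with equal depth (median -0.73 against -0.45, adjusted p = 0.0268), with fry (adjusted p = 0.00137), without wild-type replicate 1 (median -0.71, adjusted p = 0.0155) and without wild-type replicate 4 (median -0.73, adjusted p = 0.0333). Of 20 fibroblast genes 9 were tested, with Gsn lower (-1.04) and S100a4 higher (0.42; 1 and 1 adjusted over the list alone; camera adjusted p = 0.244; fry passed as lower, adjusted p = 0.00473). Only 4 leukocyte and 4 endothelial genes reached the filter, and the table held 0 of 13 mitochondrially encoded genes, so these 3 lists were not tested.

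**Figure D3:**
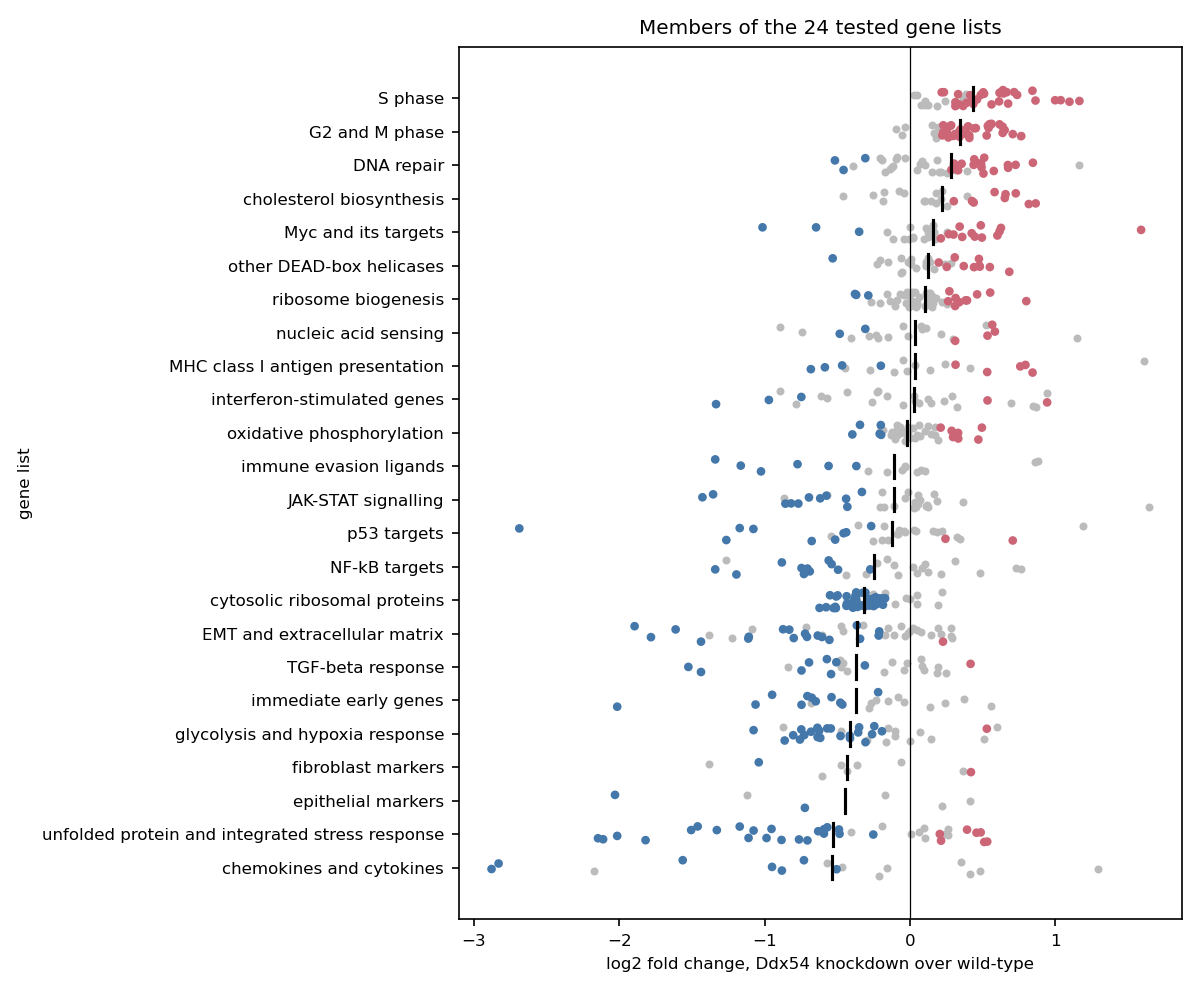
Log2 fold change (knockdown over wild-type) of each tested member of the 24 tested gene lists, ordered by their median, which is the black bar. Red and blue points passed an adjusted p of 0.05 as higher and lower, and grey points did not. The S phase list has its median at 0.43 and the stress response list at -0.53.

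Of the 24 lists, 6 were higher, 11 were lower and 7 did not pass with the preset correlation, and 9 of the 17 calls held with an estimated correlation. The lists share members, for example Junb, and are not independent. Ddit4 of the glycolysis and hypoxia list and Sesn2 of the p53 list are also members of the stress response list. Their falls are thus not separate findings of those lists.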

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

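In the wild-type group of 4, genes from the naming rule, list means, library totals, gene counts and the Rn45s share were searched for a library that stood apart from the other wild-type libraries. Of 138 quantities, 8 had such a library, where chance gives about 6.9. Wild-type 2 stood apart for Ccl7, at 4.48 CPM against 2.34 to 2.61 in the others, for Enox1, at 17.3 CPM against 25.6 to 27.1, and for Plvap, at 2.99 CPM against 0.49 to 0.89. Wild-type 4 stood apart for Cdc6, at 37.0 CPM against 28.5 to 29.3, and for Tgfbi, at 8.47 CPM against 2.45 to 3.33. Wild-type 1 had a glycolysis and hypoxia list mean of -0.079 against 0.20 to 0.25 log2 units. Wild-type 3 had 3.66 CPM of Krt19 against 4.52 to 4.69 and 18.4 CPM of Mmp13 against 12.4 to 13.4. Ccl7 lost its call without wild-type replicate 2 (log2 fold change -1.29, adjusted p = 0.124), and also, with folds nearer the reported -1.56, with limma-voom (-1.47, adjusted p = 0.0594) and without Ddx54 knockdown replicate 1 (-1.62, adjusted p = 0.0554), 2 (-1.51, adjusted p = 0.0807) or 3 (-1.55, adjusted p = 0.071). Tgfbi lost its call without wild-type replicate 4 (-0.99, adjusted p = 0.233), and also with limma-voom (-1.67, adjusted p = 0.0502), without Ddx54 knockdown replicate 1 (-1.35, adjusted p = 0.112) and without Ddx54 knockdown replicate 3 (-1.11, adjusted p = 0.119). The reported fold of Tgfbi was -1.52, and without Ddx54 knockdown replicate 2 it was -2.45 with the call kept. With the replicate number as a block (edgeR), Ccl7 (-1.56, adjusted p = 0.0781) and Tgfbi (-1.26, adjusted p = 0.106) lost their calls as well.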

How the results depend on the processing

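The correction for GC content and length, the removal of Rn45s and the trimmed Myc list were chosen after seeing the data; the other settings were planned. Genes higher in knockdown numbered 1222 to 1754 over all settings and genes lower 1409 to 1860, each within 1.5 times the reported count. With DESeq2 1617 of the 1635 higher genes and 1752 of the 1770 lower genes were shared. The fewest were shared without Ddx54 knockdown replicate 3, 1191 higher and 1362 lower. Changes of at least 1 log2 unit numbered 84 to 161 higher and 213 to 285 lower. Without Ddx54 knockdown replicate 1, 76 of the 122 such higher genes were shared. The Ddx54 log2 fold change stayed between -0.93 and -0.82. With an estimated correlation the lists lower in knockdown dropped from 11 to 5 and the lists higher from 6 to 4. For S phase the estimate was -0.015, below the preset 0.01, yet its camera adjusted p rose from 5.48e-19 to 0.0026. The TGF-beta (-0.019) and p53 (0.0015) lists also had estimates below 0.01 and lost their calls. Correlation between members therefore does not account for the higher adjusted p of S phase, and the cause in other lists was not tested. The preset and estimated settings thus differ in more than the correlation. A call lost with an estimated correlation is not by itself a sign of correlation between members. With fry the lists numbered 14 lower and 7 higher, 4 lists gaining a call. Of 107 other genes taken by the naming rule with a call, 92 kept it under every setting run on them. Over all 113 genes of that rule, with a call or not, 0 of 1916 values reversed. The remaining 15 lost it at least once, in most cases when 1 library was left out, which leaves fewer samples. Of 17 lists with a call, 9 kept it under every setting, and 0 of 432 values for lists reversed, where a reversal needs a call on at least 1 side. The trimmed Myc list kept its call with the preset correlation (adjusted p = 0.0107) and lost it with an estimated correlation (adjusted p = 0.185), as the full list did (adjusted p = 0.0916). The replicate number as a block gave 1375 genes higher and 1487 lower, and a list count of 6 and 11. No sign of pairing by number was seen. Same-number libraries deviated with correlations of -0.034, -0.027 and -0.006 across genes, and 0 of the 3 knockdown libraries correlated best with its own number. Libraries of unlike number reached at most 0.024, so a weak shared batch is not excluded. Wild-type replicate 4 has no knockdown partner, so the block leaves fewer samples to compare. The simulation recovered 44.8% of changes of 0.5 log2 units at these depths and sample numbers, and did not separate depth from sample number. It changed far fewer genes than passed in the real comparison, so this recovery need not hold there. Thinning to equal depth gave 1618 genes higher and 1790 lower.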

Other observations

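The tests of the count variance, of a shift shared by ribosomal protein genes, and of the lists of tRNA synthetases, amino acid synthesis, proteasome, splicing proteins and iron were chosen after the result was seen. Aminoacyl-tRNA synthetases had 14 of 20 members lower and 1 higher (median log2 fold change -0.32, camera adjusted p = 7.41e-07), and enzymes of amino acid synthesis 10 of 15 lower (-0.36, adjusted p = 5.45e-09). Proteasome subunits had 17 of 31 higher (0.22, adjusted p = 7.12e-06), hnRNP and SR splicing proteins 17 of 30 higher (0.32, adjusted p = 3.64e-08), and iron-handling genes 4 of 12 higher, Tfrc among them, and 1 lower (0.29, adjusted p = 0.0148). With an estimated correlation these 5 adjusted p values were 0.0517 to 0.0554. Since the lists were picked from the values, their p values are not independent evidence. Some of the enzymes of amino acid synthesis that fell are also members of the stress response list. Of 136 windows of 20 megabases with at least 20 genes, 0 passed with camera (edgeR counts, smallest adjusted p = 0.956) and 6 had an unadjusted p under 0.05.

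All 35 splits of the 7 libraries into 3 and 4 were refitted. For genes higher, the real split gave 1635 and the highest other 43, and for genes lower 1770 against 76. For changes of at least 1 log2 unit the counts were 122 against 6 and 242 against 17. In each of these 4 cases 1 of the 35 splits, the real split, gave as many, which argues against a random grouping of these 7 libraries. Every other split puts knockdown and wild-type libraries together in a group, so a real difference widens the spread there and lowers the count. A chance difference between cultures or batches is not addressed, since the replicates may be technical. For lists lower, 11 against 9, the real split was also the only 1. For lists higher, 6 of the 35 splits gave as many as the real 6, up to 10. Of the 5 others, 4 set 3 wild-type libraries against the rest, and 8 to 10 lists were higher there, nearly all of them lists that are lower in the real split. These splits hold the real difference turned round, so this count does not decide about a random grouping for the lists higher.

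Cell cycle lists were higher while stress, glycolysis and immediate early lists were lower. A correction for GC content and transcript length left all 5 lists past the threshold, and the list that moved most kept 79.2% of its median, so base composition and length are not the whole cause. Wild-type cultures that were denser at harvest may give this pattern, in which case YAP targets would be higher in knockdown. They leaned lower with an adjusted p = 0.0955 (camera on edgeR counts), which does not decide. An effect of lowered Ddx54 stays open, untested, since the labels give 1 knockdown group, no second shRNA and no rescue.

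Within groups the variance of counts was about 4 to 6 times the mean at low counts, 5.45 in wild-type and 4.43 in knockdown between 10 and 30 counts. The ratio rose by at most 1.27 times up to 300 to 1000 counts, while the median count rose by 30.6 and 31.5 times, and above 10000 counts it reached 54.2 and 21.1. Repeated reads of the same molecules may produce such a flat ratio. A constant relative difference between cultures would raise the ratio less 1 with the mean, but it rose by at most 1.34 times. Counting both mates of a pair would give a ratio near 2, and the lower group had 3.88 between 30 and 100 counts.

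Cytosolic ribosomal protein genes were lower. After the correction for GC content and length their median log2 fold change was -0.24, 77.2% of its size before, and 40 of 54 members were still lower, so that trend is not the whole cause. A shift shared by the list from library to library may account for it. The estimated correlation between members was 0.47, and the list's adjusted p with it was 0.162 (camera). The list means of the groups did not overlap, so this shift cannot be told apart from an effect of the knockdown, which was not tested separately.

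A single library held at least 500 counts and at least 10 times the next library for 3 genes, named after their values were seen. Trim12c had 4111 counts in Ddx54 knockdown 2 and at most 52 elsewhere, Gfra3 had 577 in wild-type 2 and 0 elsewhere, and Nhlh2 had 552 in wild-type 4 and at most 3 elsewhere.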
